A study of Mus musculus with 10 samples.

How the data were processed

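RNA of neutrophils enriched from the bone marrow of C57BL/6 mice on a Percoll density gradient was measured on 10 Affymetrix Mouse Gene ST arrays. The design crosses genotype (wild type or knockout of Lcn2, the gene of the iron-carrier-binding granule protein lipocalin 2) with stimulation by fMLP, a formylated bacterial-type peptide that attracts and activates neutrophils. There were 3 arrays of unstimulated wild type cells, 3 of unstimulated knockout cells, 2 of wild type cells after fMLP and 2 of knockout cells after fMLP (10 micromolar for 20 minutes at 37 degrees). The labels do not say whether the replicates were separate animals, nor whether the unstimulated cells were also kept at 37 degrees. No array was left out of the main results.

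The deposited values are RMA signals, made by the authors in Affymetrix Expression Console, and were taken as log2 from their range, since the log base is not stated. RMA subtracts background, makes the value distributions of the arrays processed together alike, and summarises the probes of each probe set. Whether all arrays were processed in 1 run is not stated. The table holds 35556 probe sets, of which 21789 name 1 gene, 1621 name several and 12146 name none in the array annotation. Of the probe sets with 1 gene, 21698 carry a symbol of the reference gene table, and 0 symbols had to be updated. For each of the 19938 genes the probe set with the highest mean over all arrays was used (999 genes have several), and a gene was tested if at least 2 arrays lay above the median of all values, 8.18 on the log2 scale. This left 14070 genes. Arrays have no read depth, and their number limits the precision: exact permutation could give no p below 0.1 for 3 arrays against 3 and none below 0.333 for 2 against 2.

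All 10 arrays were fitted together with limma version 3.58.1 in R version 4.3.3, with a coefficient per group (6 residual degrees of freedom) and moderated variances. The comparisons were knockout against wild type without and with fMLP, fMLP against unstimulated in each genotype, the difference of the fMLP responses between genotypes (the interaction), and the averages of each factor over the other. Tests were two-sided, with p values adjusted by Benjamini-Hochberg over all tested genes and called below 0.05. A log2 difference below 0 means lower in the knockout or lower after fMLP.

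Gene lists were 27, drawn up from general knowledge: primary, secondary and tertiary granule genes, chemoattractant signalling, adhesion and integrins, NADPH oxidase, pattern recognition, immediate early genes, NF-kB targets with cytokines and chemokines, STAT3 signalling, interferon response, iron handling, antioxidant defence, apoptosis, glycolysis, mitochondrial respiration, heat shock, proliferation, and 9 lists of other cell types (erythroid, B, T and NK, monocyte and macrophage, dendritic, eosinophil with basophil and mast cell, megakaryocyte, progenitor, stromal and endothelial). Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists, with camera at an estimated correlation and fry as further tests. Members were counted as called over all genes and adjusted over the list alone. Genes within 100 genes of Lcn2 on its chromosome were compared with all others by a two-sided Fisher exact test.

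The genes named were picked by rule: in each comparison the 12 called genes with the largest log2 difference in each direction whose arrays did not overlap between the groups, or, with fewer than 5 called, the 10 with the smallest p; Lcn2; and up to 4 members of a described list with the smallest p. Predicted genes were named only where fewer than 8 others were left. The comparisons, tests, filter, gene lists, naming rule and a set of alternatives were fixed before the data were examined. The alternatives were another quantile normalization, median centring, no filter or a stricter one (above 9.21), other ways from probe sets to genes, a variance trend with robust moderation, array weights, the replicate number as a fixed or a random block (statmod version 1.5.0), only the arrays compared, a size threshold of 1 on the log2 scale, gene-wise tests without moderation, and leaving out each array in turn.

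The arrays fell into 2 sets with different value distributions. Array set 1 holds the 4 arrays of unstimulated replicates 1 and 2, and array set 2 holds unstimulated replicate 3 of both genotypes with the 4 fMLP arrays. The sets were told apart by an interquartile range below or above 2. After the data had been seen, alternatives were added with the array set as a block, within each set, and without fMLP knockout replicate 2, which stands apart from the other fMLP arrays. With the block, the fMLP difference averaged over genotype is that between the fMLP arrays and the 2 unstimulated arrays of set 2. The fMLP difference of a single genotype also draws on its set 1 arrays, since the difference between the sets is estimated over both genotypes together. The labels give replicate numbers. Across genes, deviations from the group mean were correlated between wild type and knockout arrays of the same number. For unstimulated replicates 1, 2 and 3 the values were 0.949, 0.929 and 0.988, against 0.0598 after fMLP. Replicates 1 and 2 lie in set 1 and replicate 3 in set 2, so these 3 values hold the difference between the sets. Within set 1 the value was 0.464. After fMLP each group has 2 arrays, whose deviations mirror each other, and in the knockout they hold the deviation of replicate 2. The 0.0598 therefore does not show that fMLP arrays of the same number were unrelated. For the fMLP comparisons the replicate block sets fMLP arrays against set 1 arrays of the same number, so the array set block was preferred there.

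The fits were tested on simulated data with 14070 genes, of which 200 were changed, and with the 2 array sets. For the unstimulated genotype comparison, 0 of 67 genes changed by 1 on the log2 scale and 28 of 66 changed by 2 were called, with 0 false calls; with the block these shares were 80.6% and 100%, with 5 false calls. For the fMLP average, 25.4% and 69.7% were called without the block, with 0 false calls, and 83.6% and 97.0% with it, with 4 false calls. In the simulation a gene had the same spread on every array, and no array stood apart as fMLP knockout replicate 2 does. These shares and false calls therefore need not hold for the real arrays. A list of 40 genes shifted by 0.5 gave an adjusted camera p of 2.9e-37 for the fMLP average with the block and 0.00158 with an estimated correlation, and 0.00115 and 0.0790 without the block, so that the list was missed with an estimated correlation there; of the other 26 lists 0 were called. The simulated genes varied independently of each other, so this 0 says nothing about false calls of lists whose genes vary together. In the real data within set 1, the estimated correlation was 0.757 for erythroid genes and 0.535 for secondary granule genes. Figures were drawn with Python version 3.11.15 and matplotlib version 3.10.9.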

Results

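Gene expression of bone marrow neutrophils was measured in 4 groups: unstimulated wild type cells (3 arrays), unstimulated Lcn2 knockout cells (3 arrays), wild type cells after fMLP (2 arrays) and knockout cells after fMLP (2 arrays). The labels give the cells as from female mice 10 weeks old. The series asks what lipocalin 2 does in resting and in fMLP-stimulated neutrophils. The arrays differed in the shape of their values. On the 4 arrays of unstimulated replicates 1 and 2 (array set 1), the interquartile range of all probe sets was 1.64 to 1.68 on the log2 scale, and on the other 6 arrays (array set 2) it was 2.47 to 2.59. Correlations across probe sets were 0.977 to 0.988 within set 1, 0.935 to 0.996 within set 2 and 0.75 to 0.813 between the sets, and the component that separated the sets held 86.7% of the variance. Among the unstimulated arrays, the 4985 genes brightest on set 2 had a median difference of -1.46 between set 1 and set 2. The 1027 olfactory receptor genes, which sense odours in the nose, were higher on set 1 by a median of 1.35. Both genotypes have unstimulated arrays in both sets, so the genotype comparisons were balanced over the sets, but no fMLP array lies in set 1.

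**Figure D1:**
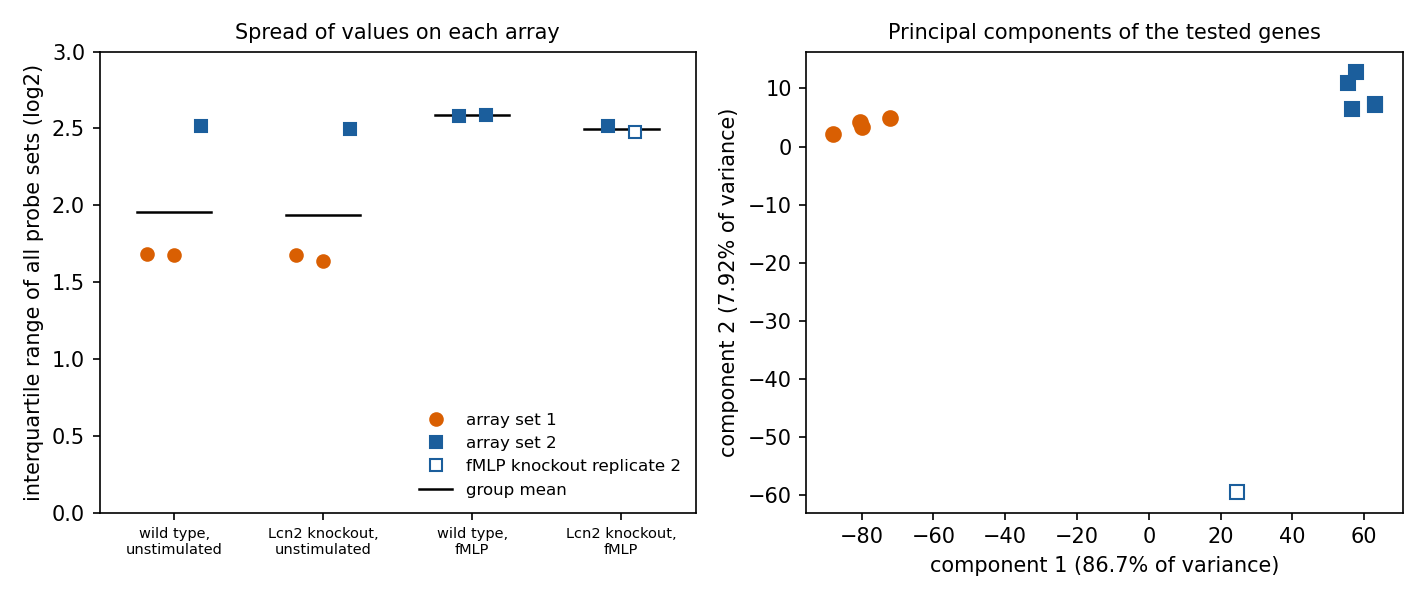
Left, the interquartile range of all probe sets on each array (log2), by group; right, the first 2 principal components of the tested genes, each point being 1 array. The 4 arrays of set 1 (circles) lie between 1.64 and 1.68 and the 6 arrays of set 2 (squares) between 2.47 and 2.59, and fMLP knockout replicate 2 (open square) stands apart on the component that holds 7.92% of the variance.

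Replicate 2 of the fMLP knockout cells differed from the other 3 fMLP arrays. It carried high signals for neuron genes. Snap25, which encodes a protein of synaptic vesicle release, reached 13.43 against 7.36 to 8.78 on the other arrays, and Syt1, Stmn2 and Camk2a reached 11.97, 11.79 and 11.56. Of 32 further neuron genes with a probe set, which do not include these 4, 32 were higher on this array than the mean of the other fMLP arrays, by a median of 2.33 on the log2 scale, against 0.0856 for 14 liver genes and 0.114 for 15 skeletal muscle genes. These 3 lists were drawn up after this array had been seen. In all, 695 tested genes were more than 1 higher and 659 more than 1 lower on this array, and the median deviation of every list but the stromal one was below 0, among them -1.10 for interferon response, -0.97 for B cell, -0.96 for pattern recognition and -0.95 for erythroid genes. The counts of genes called in the comparisons with fMLP arrays are therefore also given without it.

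**Figure D2:**
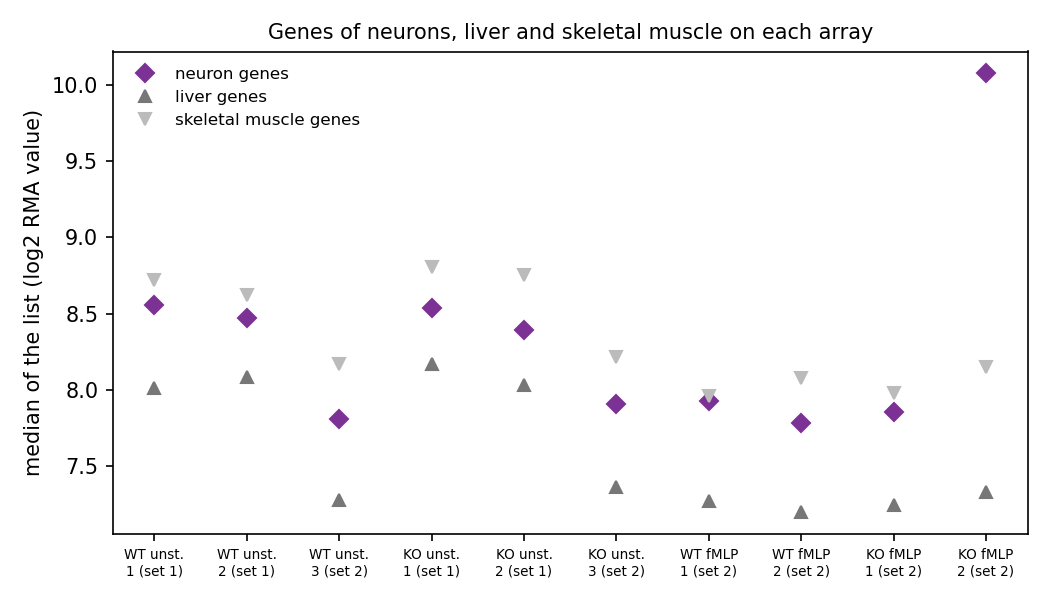
Median log2 signal of 32 neuron genes, 14 liver genes and 15 skeletal muscle genes on each array. The neuron genes reached 10.1 on fMLP knockout replicate 2, against 7.79 to 7.93 on the other arrays of set 2.

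Lcn2 itself (Entrez gene 16819, chromosome 2) encodes the secondary granule protein lipocalin 2. It was near the top of the signal range in wild type cells, and between the middle and the upper part in knockout cells. Its level was 13.94 ± 0.07 (SD, n = 3) in unstimulated wild type cells and 8.55 ± 0.58 (SD, n = 3) in unstimulated knockout cells. After fMLP it was 14.14 ± 0.02 (SD, n = 2) in wild type and 9.01 ± 0.84 (SD, n = 2) in knockout cells. Among all probe sets of an array it stood at the percentile 99.88 to 99.94 on the wild type arrays and 50.3 to 80.8 on the knockout arrays. The knockout difference was -5.39 (SE 0.37, adjusted p = 0.00367) without fMLP and -5.14 (SE 0.45, adjusted p = 0.0280) with it. Without replicate 1 or 2 of the fMLP wild type cells the second adjusted p was 0.546 or 0.570, at differences of -5.15 and -5.12. Where the probe set lies relative to the deleted part of the gene is not known from the labels.

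**Figure D3:**
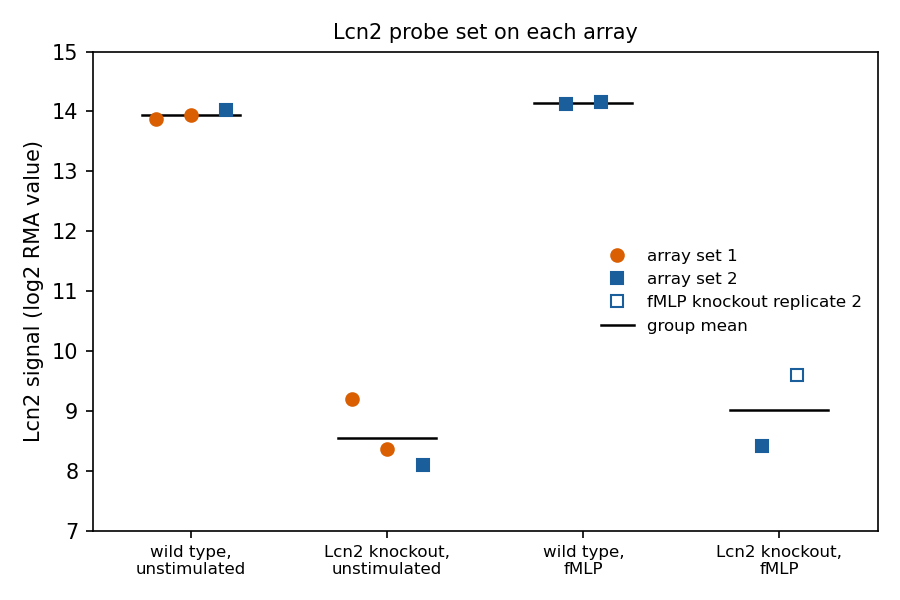
Lcn2 signal (log2 RMA value) on each of the 10 arrays by group, with the group means as lines. The 5 wild type arrays lie at 13.88 to 14.16 and the 5 knockout arrays at 8.09 to 9.60.

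In unstimulated cells, the loss of Lcn2 was the only difference between the genotypes that passed, with 1 gene of 14070 called by limma. Only 1 had an unadjusted p below 0.05, where chance alone would give 703.5. This fit leaves the difference between the array sets in its residual spread (median residual SD 0.440, against 0.163 with the array set as a block). All groups share that spread, so fMLP knockout replicate 2 adds to it here too (median residual SD 0.112 with the block and without that array). The low count therefore does not show that the genotypes were alike in other genes. The genes with the next smallest p did not pass. They were Snrnp35 (-0.33), a protein of the minor spliceosome, Timm17a (0.32), part of the mitochondrial import channel, and Ceacam2 (0.30), Dus1l (0.27), Nepro (0.34), Gstm2 (0.34), AW112010 (-0.36), Ppp3cc (0.28) and Rab13 (0.25). Camera called 6 of the 27 lists in the main fit and 12 with the array set as a block, all of them lower. The 6 lists moved together by small amounts, with 0 members called over all genes or adjusted over the list alone. Of 44 interferon response genes, which serve antiviral defence, 38 were lower in the knockout, with a median of -0.14 (camera adjusted p = 3.5e-10; adjusted p = 0.840 with an estimated correlation). Examples were Ifit3 at -0.43, Oas2 at -0.36 and Rtp4 at -0.49. All 19 secondary granule genes, the store that lipocalin 2 belongs to, were lower, with a median of -0.18 (camera adjusted p = 3.5e-07; adjusted p = 0.840 with an estimated correlation), such as Ltf at -0.32 and Lyz2 at -0.26. The array sets differed here. For the secondary granule genes the median was -0.31 within set 1, with 19 of 19 lower, and 0.015 within set 2, with 7 of 19 lower. For the interferon response genes it was -0.04 within set 1, with 27 of 44 lower and the call lost (camera adjusted p = 0.0626), and -0.29 within set 2, with 42 of 44 lower. Chemoattractant signalling genes had a median of -0.11 (camera adjusted p = 0.000849), and tertiary granule, monocyte and pattern recognition genes were also called lower, at -0.12, -0.11 and -0.08. None of these 4 calls held with an estimated correlation either (adjusted p = 0.840 for each). The tertiary granule and monocyte calls were lost within set 1 (camera adjusted p = 0.0626 and 0.233), and the chemoattractant and pattern recognition calls within set 2 (0.186 and 0.138). The 41 iron handling genes had a median of -0.03 (camera adjusted p = 0.330). With the array set as a block, Lcn2 was again the 1 gene called. Then 75 genes had an unadjusted p below 0.05, still under the 703.5 that chance alone would give. Lcn2 was also the 1 gene called by limma with the replicate number as a fixed block (-5.39, adjusted p = 0.0176). It was the 1 gene called within set 1 (-5.12, adjusted p = 0.000177). Within set 2, with 1 array per genotype, limma called 0 genes with 4 at an unadjusted p below 0.05, and Lcn2 differed by -5.92. With the block limma called 0 genes without unstimulated replicate 2 or 3 of either genotype, with 23 to 113 at an unadjusted p below 0.05.

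The fMLP arrays were marked by higher signals of immediate early genes, which respond to signals within minutes, and of an activation receptor. These arrays also differed from the unstimulated ones in sex-linked genes such as Xist. The labels do not say whether the unstimulated cells were kept at the same temperature as the fMLP cells. The differences given here therefore cannot be assigned to fMLP alone. Averaged over genotype, 10 genes were called and all were higher. Plk2, a stress-induced kinase, rose by 2.55 (SE 0.16, adjusted p = 0.00188), and Cd14, a co-receptor for bacterial lipopolysaccharide, by 2.25 (adjusted p = 0.0109). Acod1 (2.22), the itaconate-producing enzyme, and the transcription factor genes Atf3 (2.20), Nr4a1 (2.15) and Fosb (1.92) rose too. The others were the clock gene Per1 (1.77), Dusp5 (1.68), a phosphatase that acts on MAP kinases, Zbtb10 (1.24), and Xist (3.25), the RNA that silences the inactive X chromosome. At an unadjusted p below 0.05 there were 5031 genes, where chance alone would give 703.5, and the median of all genes was 0.12, but both numbers hold the difference between the array sets. With the array set as a block there were 2056 and the median was -0.02, and within set 2 there were 886. With the block 48 genes were called, 21 higher and 27 lower, including 9 of the 10. The 12 with the largest rises were Xist (3.83), Plk2 (2.44, SE 0.14), Fosl1 (2.40, SE 0.24), Atf3 (2.32), Cd14 (2.30), Egr2 (2.19), Fosb (2.01), Nr4a1 (2.00), Plk3 (1.66), Dusp5 (1.60), Snord37 (1.47) and Per1 (1.41). Acod1 stood at 1.99 with the block (adjusted p = 0.0502). Of the 21, 11 belonged to a fixed list.

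Of 48 immediate early genes, 6 were called higher over all genes and 34 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 2.6e-15; adjusted p = 0.608 with an estimated correlation). With the array set as a block, 9 rose over all genes, 26 rose and 2 fell adjusted over the list alone, and the median was 0.61 (camera adjusted p = 3.8e-19; adjusted p = 0.760 with an estimated correlation). Fosl1 stood at 7.86 on the unstimulated arrays of set 2 and at 10.26 ± 0.70 (SD, n = 4) after fMLP, and Plk2 at 7.55 and 9.99 ± 0.26 (SD, n = 4). Of 56 NF-kB targets, cytokines and chemokines, 0 were called over all genes with the block and 14 rose adjusted over the list alone, with a median of 0.21 (camera adjusted p = 9.9e-07; adjusted p = 0.774 with an estimated correlation). Differences here were 1.98 for the chemokine Ccl3, 0.86 for Ccl4, 1.51 for the NF-kB regulator Nfkbid and 1.57 for the receptor Hcar2. Without the block the medians of the immediate early and NF-kB lists lay in the same direction, and 20 NF-kB members rose adjusted over the list alone.

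**Figure D4:**
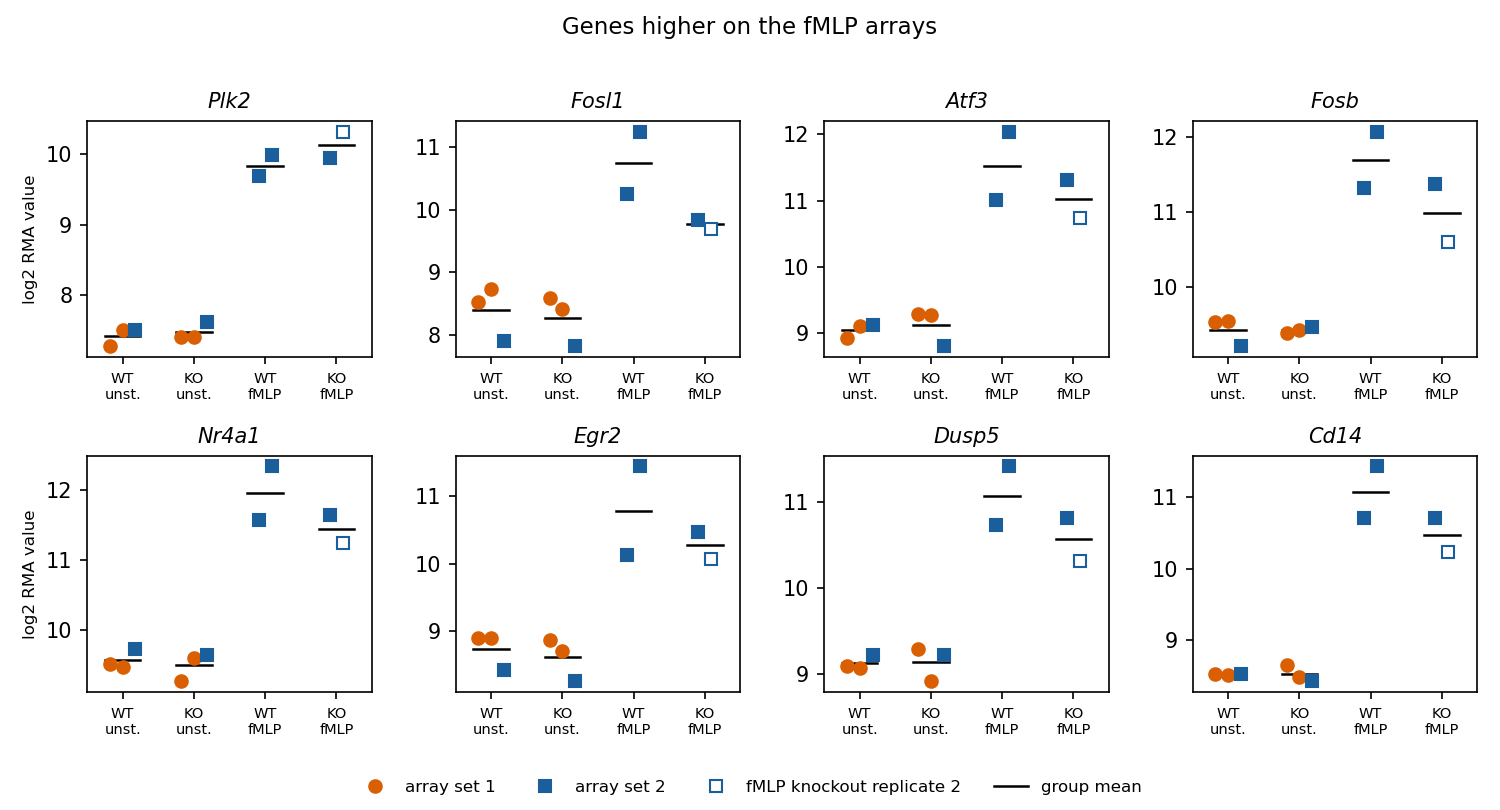
Log2 RMA values of 8 genes that rose after fMLP, 1 point per array, with group means as lines. In each panel all 4 fMLP arrays lie above all 6 unstimulated arrays of both array sets.

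Eosinophil, basophil and monocyte genes were lower on the fMLP arrays when these were set against the unstimulated arrays of the same set. Among 16 eosinophil, basophil and mast cell genes, 6 fell over all genes with the block and 9 adjusted over the list alone, with a median of -0.81 (camera adjusted p = 6.0e-09; adjusted p = 0.760 with an estimated correlation). Epx, eosinophil peroxidase, fell by 3.31 (SE 0.20, adjusted p = 0.00131), from 11.16 to 7.85 ± 0.27 (SD, n = 4). Ear6 (-3.17), Prg2 (-2.73) and Prg3 (-1.27), which encode eosinophil granule proteins, fell too, as did the basophil and mast cell protease genes Mcpt8 (-1.64) and Cpa3 (-1.57). Of 24 monocyte and macrophage genes, 3 fell over all genes and 7 adjusted over the list alone (median -0.50, camera adjusted p = 3.2e-05; adjusted p = 0.922 with an estimated correlation). The 3 were Fn1 (-2.12), the chemokine receptor gene Ccr2 (-2.08) and F13a1 (-1.74). The 13 primary granule genes, which mark immature neutrophils, had a median of -0.51 with 0 called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.774 with an estimated correlation), such as Ctsg at -1.49 and Elane at -1.20. Without the block no gene of these lists passed, with Epx at -1.48, Ear6 at -1.64, Prg2 at -1.39, Prg3 at -0.96, Mcpt8 at -0.43, Cpa3 at -0.29, Fn1 at -0.45, Ccr2 at -0.63 and F13a1 at -0.54. When fMLP knockout replicate 2 was left out of the block fit, the eosinophil, monocyte and primary granule lists had 8, 7 and 6 members that fell over all genes and 9, 9 and 7 adjusted over the list alone, while 1, 1 and 0 members rose over all genes. The medians were then -0.60, -0.24 and -0.28. The directions of the monocyte and primary granule lists rest on the block, since without it their medians were 0.20 and 0.21, while that of the eosinophil list was -0.33.

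Among the other lists, with the block, 13 T and NK cell genes had a median of 0.51 (camera adjusted p = 2.8e-05; adjusted p = 0.774 with an estimated correlation), with 0 called over all genes and 6 higher adjusted over the list alone, such as Cd8b1 at 1.14 and Cd3g at 1.36. The 46 proliferation genes had a median of -0.33 (camera adjusted p = 2.0e-05; adjusted p = 0.967 with an estimated correlation), the 19 adhesion genes -0.34 (0.00290; adjusted p = 0.927 with an estimated correlation) and the 15 progenitor genes -0.25 (0.0153; adjusted p = 0.760 with an estimated correlation), with 0 members called over all genes in each. Lower adjusted over the list alone were 2 proliferation, 0 adhesion and 2 progenitor genes. Without the block these medians were 0.83, 0.74 and 0.08. With the block and without fMLP knockout replicate 2 they were -0.18, -0.14 and -0.17, and the adhesion call was lost (camera adjusted p = 0.104). The remaining 18 lists were not called with the block. Their medians were 0.37 for B cell, 0.28 for dendritic, -0.0028 for erythroid, -0.12 for megakaryocyte and -0.09 for stromal genes. They were -0.11 for secondary and -0.21 for tertiary granule genes, -0.11 for chemoattractant signalling, -0.10 for NADPH oxidase, -0.02 for pattern recognition (with Cd14 as its 1 called member), -0.10 for STAT3 signalling and -0.02 for interferon response genes. They were 0.01 for iron handling, -0.05 for antioxidant, -0.04 for apoptosis, 0.12 for glycolysis, -0.08 for respiration and 0.04 for heat shock genes, of which Asns rose (0.76). Without the block camera called 20 lists, 18 of them higher, and 0 held with an estimated correlation (adjusted p = 0.608 for the immediate early genes).

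The fMLP arrays also differed from the unstimulated ones in sex-linked genes. Xist stood at 6.88 to 7.82 on the 6 unstimulated arrays, at 9.83 on fMLP knockout replicate 2 and at 10.97 to 11.12 on the other fMLP arrays. Eif2s3y, a gene of the Y chromosome, stood at 6.77 to 7.22 on the 4 arrays of set 1, all unstimulated, which was at or below the percentile 21.3 of their probe sets. It stood at 9.83 and 9.59 on the unstimulated arrays of set 2 and at 6.48 on fMLP knockout replicate 2. On the other fMLP arrays it stood at 5.36 to 5.44, at the percentile 7.32 to 7.91. With the block it fell by 4.04 in limma (SE 0.28, adjusted p = 0.00161), a size that rests on values near the floor. The Y-linked genes Uty and Kdm5d, which were not tested because of low signal, differed within set 2 by -1.96 and -1.17. Among further genes, the histone gene H2bc8 (-1.51) and the small nucleolar RNA gene Snora31 (-1.37) fell with the block. None of these 3 falls passed without it, with Eif2s3y at -2.24, H2bc8 at -0.0031 and Snora31 at -0.75.

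**Figure D5:**
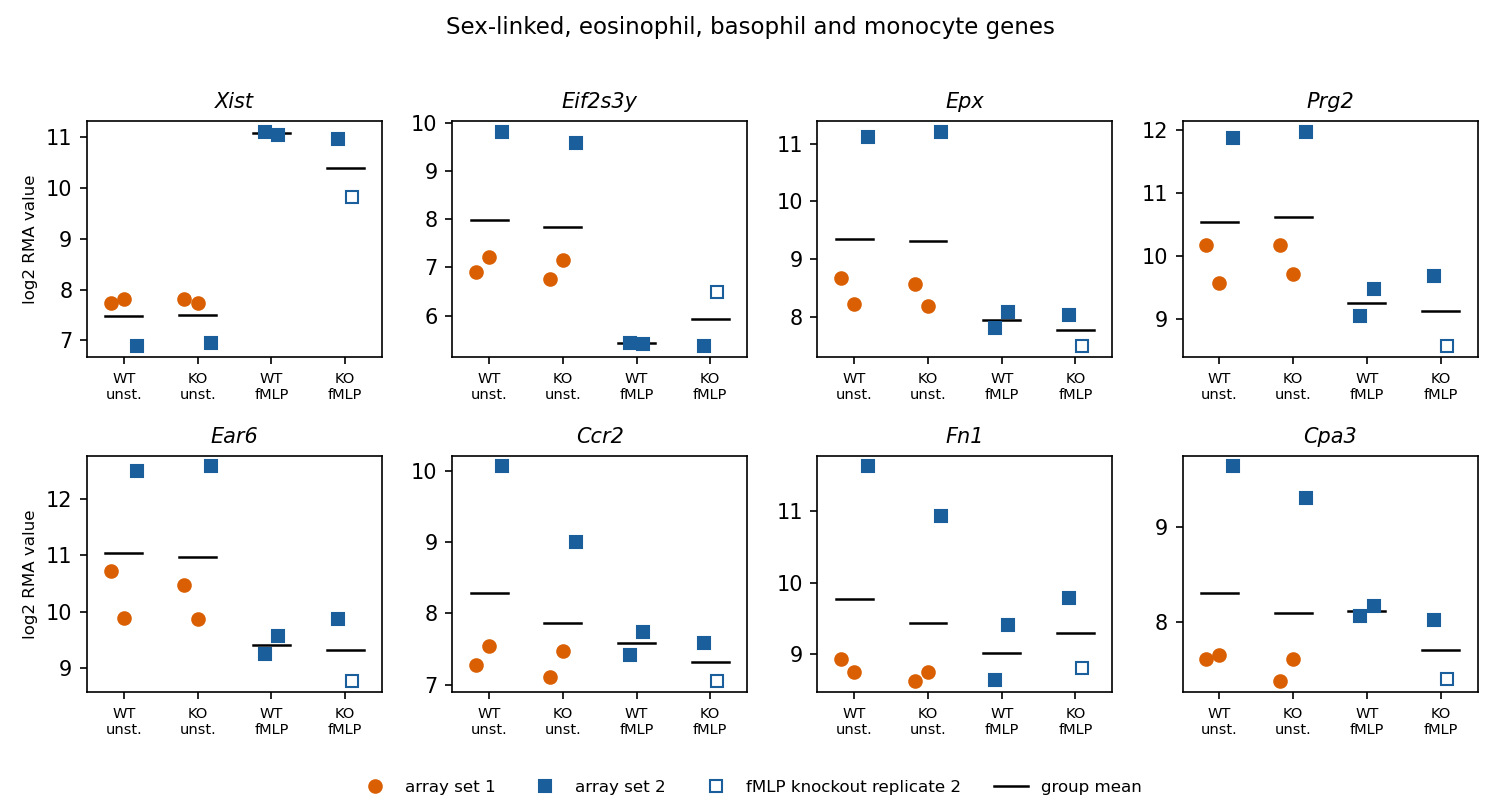
Log2 RMA values of Xist, the Y-linked gene Eif2s3y, eosinophil, basophil and mast cell genes (Epx, Prg2, Ear6, Cpa3) and monocyte genes (Ccr2, Fn1), 1 point per array, with group means as lines. In set 2 (squares) Eif2s3y is at 9.59 or above on both unstimulated arrays and at 6.48 or below on all 4 fMLP arrays.

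The count for fMLP moved with the arrays used. With the block and without fMLP knockout replicate 2, 1428 genes were called, 895 higher and 533 lower, which included all 48. Among those that rose the largest were Xist (4.11), Atf3 (2.46), Rasgef1b (2.45), Fosl1 (2.43), Cd14 (2.42), Plk2 (2.34), the early activation marker Cd69 (2.29), Egr2 (2.28), Fosb (2.21), Acod1 (2.16), Ccl3 (2.11) and Nr4a1 (2.11). Among those that fell they were Eif2s3y (-4.32), Epx (-3.17), Ear6 (-2.89), Prg2 (-2.45), the antibody-joining chain gene Jchain (-2.10), Ccr2 (-1.94), Fn1 (-1.88), Ms4a6c (-1.86), F13a1 (-1.55), Mcpt8 (-1.44), Cpa3 (-1.42) and H2bc8 (-1.33). Then 31 immediate early genes and 19 NF-kB targets rose over all genes, 35 and 29 adjusted over the list alone, with medians of 0.74 and 0.37 (camera adjusted p = 5.0e-23 and 8.8e-12; adjusted p = 0.241 with an estimated correlation for both). Of the 20 B cell genes, 13 rose and 1 fell over all genes, and 15 rose and 3 fell adjusted over the list alone (median 0.68, camera adjusted p = 4.4e-06; adjusted p = 0.431 with an estimated correlation). Of the T and NK cell genes 7 rose over all genes and 9 adjusted over the list alone. Within set 2 alone limma called 0 genes, with 886 at an unadjusted p below 0.05, and 3119 without fMLP knockout replicate 2. With the block 4055 genes were called without fMLP knockout replicate 1, 29 and 13 without fMLP wild type replicates 1 and 2, and 13 to 21 without an unstimulated array of set 1. Without unstimulated replicate 3 of wild type or knockout limma called 0, with 695 and 740 at an unadjusted p below 0.05. Without the block the count was 7661 and 8099 without these replicates, 4 and 1 without fMLP wild type replicates 1 and 2, and 1 without each array of set 1.

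In each genotype by itself 1 gene was called after fMLP, and it was Plk2: 2.43 (SE 0.23, adjusted p = 0.0461) in wild type and 2.67 (SE 0.23, adjusted p = 0.0215) in knockout cells. At an unadjusted p below 0.05 there were 1120 and 928 genes. The genes with the next smallest p did not pass. In wild type cells they were Cd14 (2.55), Nr4a1 (2.37), Xist (3.60), Fosb (2.27), Atf3 (2.49), Dusp5 (1.95), Acod1 (2.59), Fosl1 (2.36) and Plk3 (2.65). In knockout cells they were Cd14 (1.95), Nr4a1 (1.93), Xist (2.90), Zbtb10 (1.23), Atf3 (1.91), Per1 (1.73), the selenoprotein gene Selenow (1.04), Dusp5 (1.42) and Fosb (1.56). With the array set as a block, 11 genes were called in wild type cells. Xist (4.18), Fosl1 (2.83), Cd14 (2.60), Plk2 (2.32), Nr4a1 (2.22) and Snord37 (1.70) rose, and Eif2s3y (-4.36), Epx (-3.23), Prg3 (-1.19), Trappc2 (-1.13) and Derl2 (-1.09) fell. In knockout cells 12 were called. Xist (3.47), Plk2 (2.56), Snord37 (1.24) and Selenow (1.09) rose, and Eif2s3y (-3.71), Epx (-3.39), H2bc8 (-1.82), Prg3 (-1.36), 0610009B22Rik (-1.27), Trappc2 (-1.26), Cetn3 (-1.12) and Derl2 (-1.10) fell. Of the immediate early genes, 3 rose over all genes in wild type and 1 in knockout cells with the block, and 23 and 18 adjusted over the list alone, with medians of 0.72 and 0.46 (camera adjusted p = 4.0e-26 and 3.7e-11; adjusted p = 0.597 and 0.709 with an estimated correlation). Trappc2, which serves vesicle transport, and Derl2, which serves protein removal from the endoplasmic reticulum, stood above 0 without the block (0.95 and 0.60 in wild type, 0.82 and 0.59 in knockout cells), and H2bc8 was -0.31 in knockout cells. Without fMLP knockout replicate 2 the block fit called 724 genes in wild type and 303 in knockout cells, and without its replicate 1 it called 5429 in knockout cells. It called 15 and 1 in wild type cells without fMLP replicates 1 and 2, 5 in wild type and 2 in knockout cells without an unstimulated array of set 1, and 0 without unstimulated replicate 3 (325 and 614 at an unadjusted p below 0.05). Without the block, leaving out any array of the groups compared left 0 genes (179 to 8058 at an unadjusted p below 0.05), except fMLP knockout replicate 1 with 66.

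Across the 14070 tested genes the fMLP differences of the genotypes correlated (Pearson r = 0.908, Spearman rho = 0.912), but both hold the difference between the array sets. Within set 2, Pearson r was 0.525 and Spearman rho 0.454, and without fMLP knockout replicate 2 the Pearson r was 0.852. Genes are not independent replicates, so no p is given. The genotype differences without and with fMLP correlated at a Pearson r of 0.337, and at 0.317 without Lcn2. On the component that separated the array sets, each knockout array lay further towards set 1 than the wild type array of the same number. The difference with fMLP also includes fMLP knockout replicate 2, whose deviation correlated with the difference between the sets (Pearson r = 0.467). The correlation of the genotype differences therefore cannot be assigned to the genotype.

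After fMLP, Lcn2 was again the 1 gene called between knockout and wild type, with 11 genes at an unadjusted p below 0.05. It lost its limma call with the fixed replicate block (adjusted p = 0.0964) and within set 2. The genes with the next smallest p in the main fit did not pass. They were the inflammation-induced matrix-binding protein gene Tnfaip6 (-1.32), the interferon-induced gene Ifit3 (-1.34), the integrin gene Itga6 (-0.81), Adgrg7 (-0.61), Uchl1 (1.80), a deubiquitinating enzyme gene abundant in neurons, Prdx6-ps2 (-0.67), Eri3 (0.61), Arhgap35 (1.33) and Evl (0.86). With fMLP knockout replicate 2 left out, Uchl1 was 0.45, Arhgap35 0.27, Evl 0.27, Eri3 0.30, Ifit3 -0.87 and Adgrg7 -0.39. Camera called 19 of the 27 lists, 18 of them lower in the knockout, with 0 members called. Interferon response genes had a median of -0.58 and 43 of 44 were lower (camera adjusted p = 1.0e-16; adjusted p = 0.678 with an estimated correlation). Among them were Ifit1 at -1.14 and Usp18 at -0.86. Proliferation genes had a median of -0.52 (camera adjusted p = 3.2e-07), immediate early genes -0.43 (3.2e-07), with Fosl1 at -0.98 and Fosb at -0.72, pattern recognition genes -0.54 (1.0e-05) and iron handling genes -0.20 (0.0494). With an estimated correlation 0 lists held (adjusted p = 0.678 for these 4 too). On fMLP knockout replicate 2, pattern recognition and iron handling genes had median deviations of -0.96 and -0.35 from the other fMLP arrays. This array group includes that array, the one with neuron transcripts. Without it (array set as a block), Lcn2 was the 1 gene called, at -5.73, with 255 genes at an unadjusted p below 0.05, and 8 lists were called. The medians were then -0.13 for interferon response (camera adjusted p = 3.9e-06), -0.15 for proliferation (5.5e-08) and -0.15 for immediate early genes (0.00283), and B cell genes were higher (0.25, camera adjusted p = 6.2e-07). None held with an estimated correlation (adjusted p = 0.546 for these 4). Without replicate 1 of the fMLP knockout cells, which leaves that array alone in its group, 86 genes were called, and 6401 with the block. Without either fMLP wild type array limma called 0, with 14 (replicate 1) and 1 (replicate 2) at an unadjusted p below 0.05. Within set 2 and without that array, 3 genes were called: Lcn2 and the immunoglobulin light chain genes Igkv4-55 (1.28) and Igkv19-93 (1.08), which were named after their values were seen.

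For a difference of the fMLP responses between the genotypes limma called 0 genes, and 1 had an unadjusted p below 0.05 (258 with the array set as a block, also with 0 called). The genes with the smallest p were Tnfaip6 (-1.18), Eri3 (0.65), Fam83d (-0.60), Pbxip1 (-0.65), Evl (0.90), Uchl1 (1.73), the mitochondrial ADP carrier gene Slc25a4 (1.46), Sox4 (0.65), Vcam1 (-0.61) and Adgrg7 (-0.56), and none passed. Leaving out fMLP knockout replicate 2, Uchl1 was 0.37, Slc25a4 0.32, Evl 0.30, Eri3 0.35, Sox4 0.37, Pbxip1 -0.37, Vcam1 -0.36 and Adgrg7 -0.34. Camera called 16 lists, all with the fMLP difference of the knockout below that of the wild type and with 0 members called. Medians were -0.47 for proliferation (camera adjusted p = 4.5e-06), -0.44 for interferon response (1.6e-09), -0.37 for immediate early (7.5e-06) and -0.35 for NF-kB genes (4.5e-06), and adjusted p = 0.807 for each with an estimated correlation. With the block and without fMLP knockout replicate 2, limma called 0 genes, with 125 at an unadjusted p below 0.05, and camera called 4 lists: B cell (0.16), monocyte (0.16) and secondary granule genes (0.11), with the fMLP difference of the knockout above that of the wild type, and proliferation genes (-0.14), with it below. None of the 4 held with an estimated correlation (adjusted p = 0.792 for monocyte genes and 0.930 for the others). The interferon response genes then had a median of -0.0048. Without fMLP knockout replicate 1 the count was 16, and 4924 with the block. Within set 2 and without its replicate 2 it was 1, Igkv4-55 (1.60), named after its value was seen.

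Averaged over stimulation, the knockout difference in Lcn2 was -5.26 (SE 0.29, adjusted p = 0.000646) and no other gene was called, with 4 at an unadjusted p below 0.05. Those next by p were Ifit3 (-0.89), Tnfaip6 (-0.73), Itga6 (-0.51), Prdx6-ps2 (-0.40), Adgrg7 (-0.33), Arhgap35 (0.75), Uchl1 (0.94), Maf (0.30) and the sterol sensor gene Insig1 (-0.47), none of which passed. Without fMLP knockout replicate 2, Arhgap35 was 0.22, Uchl1 0.26 and Adgrg7 -0.22. Interferon response genes had a median of -0.38, with 43 of 44 lower (camera adjusted p = 6.5e-21), and secondary granule genes -0.32, with 19 of 19 lower (6.9e-05). Iron handling genes had a median of -0.15 (camera adjusted p = 0.0401). On fMLP knockout replicate 2 these genes had a median deviation of -0.35 from the other fMLP arrays. Each of the 3 lists had 0 members called and adjusted p = 0.611 with an estimated correlation. Without fMLP knockout replicate 2 and with the block, the medians were -0.13 for interferon response (camera adjusted p = 9.4e-12) and -0.15 for secondary granule genes (9.1e-06), each with adjusted p = 0.399 with an estimated correlation, and Lcn2 was the 1 gene called. Within set 2 limma called 0 genes, with 14 at an unadjusted p below 0.05, and without fMLP knockout replicate 1 the count was 20, and 5629 with the block. Of 94 tested genes within 100 genes of Lcn2 on chromosome 2, where sequence of the embryonic stem cell strain can remain beside a targeted gene, 0 were called by limma in any of the 3 genotype comparisons, and 0 had an unadjusted p below 0.05, as did only 0, 10 and 3 of the 13975 other genes, too few for a test. With the array set as a block, 0, 5 and 1 of the 94 had an unadjusted p below 0.05 in unstimulated cells, after fMLP and on average, against 74, 1176 and 771 of the others (two-sided Fisher exact p = 1, 0.352 and 0.0648).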

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

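The tests of the array sets and of a response in 1 sex for the sex-linked genes, of a smaller cell share and of the array sets for the eosinophil genes, of neural RNA for fMLP knockout replicate 2, the balanced splits and those within set 2, and all values with the array set as a block were chosen only after the results were seen.

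Camera gave 16 lists whose fMLP response differed between the genotypes, all with the fMLP difference of the knockout below that of the wild type, as a test of the difference itself, and 0 of the 16 held with an estimated correlation. With the array set as a block and without fMLP knockout replicate 2, 4 were called, of which B cell (0.16), monocyte (0.16) and secondary granule genes (0.11) had the opposite sign, and 0 of the 4 held with it. Among the 7720 tested probe sets that name no gene or several genes and are used in no comparison, 19 differed between fMLP and unstimulated arrays, 16 higher and 3 lower, and all 19 name no gene; with the array set as a block the count was 415.

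The fMLP arrays carried Xist signal and little Y-linked signal, while the unstimulated arrays of set 2 carried Eif2s3y and little Xist and those of set 1 carried no clear signal of either, although all labels give female mice. The array sets are argued against as the source, since Xist differed by 3.83 within set 2 and passed with the set as a block. A response to fMLP in cells of 1 sex would leave either Xist or the Y-linked genes unexpressed throughout, but the Y-linked genes differed by a median of -1.96 within set 2 in the opposite direction to Xist. Cells of different sex in the fMLP and the unstimulated preparations remain a candidate explanation: 4 genes that escape X inactivation had a median difference of 0.35 within set 2, with Kdm6a at 0.52, Eif2s3x at 0.54, Kdm5c at 0.18 and Ddx3x at -0.04, but none of the 4 passed with the set as a block (adjusted p = 0.338 to 0.941), so their support is weak. If the sexes differed, fMLP and the sex of the animals cannot be told apart in any stimulation comparison of these arrays.

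Eosinophil and basophil genes were lower on the fMLP arrays. The array sets as the whole source are argued against by 6 members of the list that passed with the set as a block, and a general excess of non-neutrophil cells in the unstimulated preparations by the B cell genes, whose median within set 2 was 0.37 rather than below 0. A smaller share of eosinophils and basophils in the fMLP preparations may be the reason, but the median of all 16 genes within set 2 was -0.81, between the values named for and against it, so it stays open. An effect of fMLP on these cells or their transcripts, and the sex or other features of the animals, were not tested and stay open too, since each genotype has 1 unstimulated array in set 2.

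Replicate 2 of the fMLP knockout cells stood apart from the other fMLP arrays. RNA of an unstimulated preparation as the only addition is argued against. The loss of Xist would need a share of 60.4% and the gain of Eif2s3y a share of 5.91%, a ratio of 10.2. These shares say nothing about unstimulated RNA mixed in together with other RNA, which would lower Xist as well. For more cells of a type among the 9 marker lists, the highest median deviation was 0.0583, for the stromal list, on the side named against it. This cannot exclude such cells, since the medians of all other lists lay below 0 and a general loss of signal could hide a rise. Signal loss of the kind that separates the array sets cannot be told apart from other sources. Its Pearson r with the array's deviation across genes was 0.467, between the values named for and against it. The Spearman rho, for which no values were named, was 0.558. RNA of neural tissue on this array is a candidate explanation, since 32 neuron genes, drawn up without those seen to lead its deviation, deviated by a median of 2.33, with Elavl4 at 3.82, Chn1 at 3.73, Sst at 3.68 and Rtn1 at 3.62. No biological explanation was tested, as the design gives none for 1 array of a group.

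For the unstimulated genotype comparison the 6 arrays allow 10 splits, too few for a share below 0.05; the real one called 1 gene and the highest other 0. For the genotype average there were 60 splits, the real one calling 1 gene and the highest other 0. These counts were the same with the array set as a block, and among the 36 splits that leave the array sets balanced the highest other was also 0. In both comparisons the gene was Lcn2, the knocked-out gene, whose arrays lie apart between the genotypes. The splits therefore say nothing about other genes, and they exchange arrays between replicate numbers. For the fMLP average, 2 of 100 splits, the real one with 10 genes included, called at least as many as it, and the highest other called 11718. That other split labels the 4 set 1 arrays as fMLP, so it follows the array sets and points to a structure of the samples. All fMLP arrays lie in set 2, and only 9 splits keep to that set, too few for a share below 0.05. Among these the highest other called 0, also with the array set as a block, where the real one called 48.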

How the results depend on the processing

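Alternatives with the array set, within a set or without fMLP knockout replicate 2, and leaving out arrays with the set as a block, were chosen after seeing the data. Of 2607 alternative values, 1869 were counted as the same, 476 lost a call, 106 gained one, 123 moved and 33 reversed. For single genes and lists, the same means an unchanged direction and side of the threshold. For counts and correlations it means a value close to the main one. Many of the genes did not pass in the main fit, and those that stayed uncalled count as the same. Where no reason is given the cause was not tested; fits within a set or of only the arrays compared have fewer arrays. Arrays have no depth, and signal over background limits them: set 1 spans a narrower range. Tests of an arm left with 1 array assume that it varies like the other groups.

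Counts are given in the order unstimulated genotype, fMLP genotype, fMLP in wild type, fMLP in knockout, interaction, genotype average, fMLP average, for which the main counts were 1, 1, 1, 1, 0, 1 and 10; comparisons not named kept theirs. Within set 2 all counts were 0 (the interaction was 0 before). Within set 2 without fMLP knockout replicate 2 the last 6 counts were 3, 1524, 938, 1, 2 and 3119. With the set as a block the fMLP counts were 11, 12 and 48, and 724, 303 and 1428 without that array. Array weights gave 11710, 9395 and 11762 for the fMLP counts, the fixed replicate block 11384, 10444 and 11758 and the random one 11614, 10665 and 11949. Both blocks set fMLP arrays against set 1 arrays of the same number, and for the weights the cause was not tested. The fixed replicate block gave 0 for the fMLP genotype count, as did a variance trend with robust moderation, which gave 3 for the fMLP average. Only the arrays compared gave 0 for the fMLP genotype count and for fMLP in each genotype. Gene-wise tests gave 0 for both genotype counts and for fMLP in knockout cells. For fMLP in wild type cells, median centring gave 3 and the stricter filter and all probe sets 0; in knockout cells median centring and a further quantile normalization gave 0. The other filters, other ways to genes, the size threshold and wider or narrower windows around Lcn2 kept the counts.

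Leaving out 1 array of the groups compared at a time, the counts ranged from 1 to 1, 0 to 86, 0 to 0, 0 to 66, 0 to 16, 1 to 20 and 1 to 8099 in the same order. The highest fMLP average counts came without unstimulated replicate 3 of wild type (7661) or knockout (8099), while leaving out replicate 1 or 2 of either genotype or fMLP wild type replicate 2 gave 1, fMLP wild type replicate 1 gave 4, and fMLP knockout replicates 1 and 2 gave 15 and 7. With the set as a block the ranges, again over the arrays of the groups compared, were 0 to 1, 0 to 6401, 0 to 15, 0 to 5429, 0 to 4924, 1 to 5629 and 0 to 4055; the highest of those that include fMLP knockout arrays came without fMLP knockout replicate 1, which leaves only the array with neuron transcripts in its group. The 15 for fMLP in wild type cells came without fMLP wild type replicate 1, and the 1 for the unstimulated genotype comparison without unstimulated replicate 1 of either genotype. Without fMLP knockout replicate 2, not among the arrays compared there, that count was 724. In that fit the fMLP average was 13, 13 and 0 without wild type unstimulated replicates 1, 2 and 3, 17, 21 and 0 without those of the knockout, and 29 and 13 without fMLP wild type replicates 1 and 2.

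Lcn2 differed by -5.92 within set 2 without fMLP (adjusted p = 1) and by -5.72 to -5.16 with 1 array left out. After fMLP it stayed at -5.14 and lost its call with the trend and robust moderation, the fixed replicate block and within set 2 (adjusted p = 0.132, 0.0964 and 0.683), and ranged from -5.73 to -4.54 with 1 array left out. The correlation of fMLP responses was 0.525 within set 2 and 0.667 (without fMLP knockout replicate 1) to 0.983 (without replicate 2) with 1 array left out.

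The reversed directions given here came with the array set, in the last case together with leaving out fMLP knockout replicate 2. Leaving out that array also gave interactions of B cell, monocyte and secondary granule genes, given above. Their sign was opposite to that of the lists called in the main fit. Rab13 was -0.00136 within set 2. Without the block Trappc2 was 0.95 and Derl2 0.60 in wild type and 0.82 and 0.59 in knockout cells, Jchain was 0.10 and Ms4a6c 0.58. With the block or within set 2, list medians after fMLP were -0.50 for monocyte, -0.51 for primary granule, -0.33 for proliferation, -0.25 for progenitor and -0.34 for adhesion genes, and without fMLP knockout replicate 2 they were -0.24, -0.28, -0.18, -0.17 and -0.14. Within set 2 secondary granule genes were 0.015 and iron handling genes 0.011 in the unstimulated knockout, and the interaction of interferon response genes was 0.20 without that array.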
